A study of Homo sapiens with 3 samples.

How the data were processed

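Total RNA from 3 cultures of the osteosarcoma line MNNG/HOS was labelled with Cy3 and hybridised to 1 single-colour expression array each, per the labels' protocols. The groups were untreated adherent cells cultured for 5 days, cells given 4 ng/mL TGF-beta1 for 3 days, and floating spheres collected after 5 days of 4 ng/mL TGF-beta1. The labels do not say which fraction of the day 3 culture was collected. With 1 array per group there were no replicates, so neither a test nor a standard error between samples was possible, and precision is limited by the number of arrays.

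The authors deposited 1 intensity per probe set and array, made with RMA per the submitters' processing notes. The deposited intensity values were on a linear scale, from 2.37 to 51530, with nearly the same distribution on each array. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a set. This would hide any difference that affects most genes in the same direction. RMA usually ends on a log scale; how the linear values were obtained, the version of the method, the scanner and the annotation build are not given in the sources used here. No detection calls were used here, so it is not known which low values exceed background. Background correction compresses or inflates differences at low intensity, and folds that start from low values are uncertain for that reason.

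The log2 of each deposited intensity was taken with no offset. Of 45033 probe sets, 18188 were named by the array platform's gene table, which was updated to current symbols through gene identifiers, and 678 more by an unversioned RefSeq transcript accession in a gene table of assembly GRCh38.p14. No probe set had several symbols, and 26167 remained unnamed here and entered no gene value. Coordinates were not used, since the build behind the array was not stated. A gene's value was the mean log2 over its probe sets, which gave 17185 genes, of which 1349 had more than 1 probe set. Genes were counted when their highest value over the 3 arrays reached the median of all gene values, an intensity of 685 (log2 9.42), which left 9285 genes; gene lists and the counts of their members were not filtered. Members of near-identical families, such as metallothioneins, histones, hair keratins and AKR1C genes, can share signal between probes.

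All analysis choices that follow were fixed before the data were examined unless stated otherwise. For each pair of arrays the log2 difference was the first named array minus the second. A fixed rule of size, at least 2-fold, replaced a test. For 42 gene lists the median log2 difference of all measured members, including those below the level filter, was compared with 10000 random lists of the same size drawn from the same 20 bins of mean level, and a list stood apart when its median lay under the 2.5 or over the 97.5 percentile. This describes these arrays and does not test the conditions. The lists covered TGF-beta and BMP signalling, stem cell, lineage and matrix genes, metabolism, cell cycle, stress and immune responses, and markers of other cell types; a few genes stand in more than 1 list. The overlap of the comparisons that share the untreated array was set against independent lists and against 1000 shuffles of each gene's 3 values among the arrays.

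Genes named in the text were chosen by a rule with 3 parts. The first took the 12 genes with the highest and the 12 with the lowest difference per comparison, among genes past the level filter and past 2-fold whose probe sets all differed in the same direction, leaving out provisional symbols and olfactory receptors. The second took up to 4 members of each described list with the largest differences. The third always included POU5F1, NANOG, SOX2, KLF4, MYC, TGFB1, TGFBR1, TGFBR2, SMAD7, ID1, RUNX2, ALPL, SPP1, COL1A1, CD44, PROM1, ABCG2, ALDH1A1, SNAI1, SNAI2, CDH1, VIM, MKI67, CDKN1A and VEGFA, and 1 more gene that is not reported here.

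The procedure was tested on simulated data in which noise was drawn at the robust spread of the real differences in each level bin. That spread contains real effects, so it is likely to overstate noise. For day 3 against untreated cells, 92% of 100 genes changed 3-fold and 10% of 100 genes changed 1.5-fold passed the 2-fold rule, among 17185 genes. The values were 86% and 16% for the spheres against untreated cells and 91% and 19% for the spheres against day 3. Of 42 unchanged lists, 3, 3 and 1 lay outside the central 95% in the 3 simulated comparisons. Their differences were shuffled among genes of the same level bin, so a share of this size is largely set by construction. Lists whose genes vary together were not simulated.

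Alternatives fixed in advance were no level filter, a filter at the upper quartile, the brightest probe set or the median over probe sets per gene, centring each array on its median, quantile normalization, adding 64 to each intensity before log2, thresholds of 1.5-fold and 3-fold, and random lists not matched on level. A running median over 501 genes of similar level, subtracted per array, and list medians over members past the level filter were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with figures drawn in matplotlib 3.10.9.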

Results

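Gene expression was measured in MNNG/HOS, an established human osteosarcoma cell line, grown without serum. Under these conditions part of the culture leaves the dish and forms floating spheres, called sarcospheres. The spheres were first taken away, and the adherent cells that stayed behind were then cultured in 1 of 3 ways. One culture was kept without added factor for 5 days, a second received transforming growth factor beta 1 (TGF-beta1) at 4 ng/mL for 3 days, and another received the same dose for 5 days. From the 5-day treated culture only the newly floating spheres were collected, which the submitters abbreviate as iOSCs, and the 3-day culture was called mesophase. Total RNA from each culture was hybridised to 1 single-colour array, so there were 3 arrays and no replicates.

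The design implies 3 comparisons: day 3 of TGF-beta1 against untreated cells, day 5 spheres against untreated cells, and day 5 spheres against day 3. No difference given here has a replicate check, and no p-value was computed. A gene was called higher or lower when its values on 2 arrays differed by at least 2-fold. The numbers of genes over the whole array include only genes whose highest value reached an intensity of 685, the level filter, while gene lists and their counts include all measured members. The median difference of a gene list was set against 10000 random lists of the same size and expression level, which describes these arrays only. The 3 arrays had median intensities of 455 in untreated cells, 437 at day 3 and 445 in day 5 spheres. The highest value on each lay between 50548 and 51530, and Pearson's r between pairs of arrays across all probe sets was 0.977 to 0.979. Genes are not independent replicates, and 1 array per culture limits the precision of every value. Treatment, day of culture and possibly the fraction of cells collected differ together between day 3 and untreated cells. Treatment and the fraction differ between spheres and untreated cells, which were both cultured for 5 days. Days of treatment and possibly the fraction differ between spheres and day 3.

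The first comparison asks how the culture after 3 days of TGF-beta1 differed from untreated adherent cells. Extracellular matrix genes, known targets of TGF-beta, immediate early transcription factors and interferon-response genes were higher than in untreated cells, while DNA replication and mitosis genes were slightly lower. COL1A1, which encodes a chain of type I collagen, was 6.14-fold higher, at an intensity of 10781 against 1755. FOS, a subunit of the transcription factor AP-1, was 8.84-fold higher, and OASL, an interferon-induced gene, was 6.52-fold higher. ID3, an inhibitor of basic helix-loop-helix transcription factors and a target of bone morphogenetic protein (BMP) signalling, was 4.97-fold lower, while BMP targets as a list did not stand apart, with a median of -0.13 against -0.29 to 0.28, and BAMBI, another target and a decoy receptor gene, was 2.17-fold higher. Of 9285 genes compared, 427 (4.60%) were at least 2-fold higher at day 3 and 319 (3.44%) were at least 2-fold lower.

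Of 22 measured targets of TGF-beta, 7 were at least 2-fold higher at day 3 and 0 at least 2-fold lower, with 16 above 0. The list's median log2 difference was 0.48, against -0.21 to 0.14 for the central 95% of random lists. TNFAIP6, which encodes a hyaluronan-binding secreted protein, was 59.0-fold higher, from an intensity of 12.9 that lay among the lowest values of the array. JUNB was 4.44-fold higher, BHLHE40 3.27-fold and PMEPA1, a feedback inhibitor of the pathway, 2.58-fold. SMAD7, the inhibitory SMAD induced by TGF-beta, was 2.47-fold higher. TGFB1 itself was 2.07-fold higher, with intensities of 5454 untreated and 11309.6 at day 3. The receptors TGFBR1 and TGFBR2 differed by log2 values of 0.06 and -0.15. Among the 22 measured ligands, receptors and SMADs of the pathway the median was -0.12, within the range of random lists. In that list FST, which encodes the activin antagonist follistatin, was 8.02-fold lower, TGFB2 14.4-fold lower and SMAD3 2.62-fold lower, while the BMP receptor gene BMPR2 was 2.54-fold higher. TGFB2 was not past the level filter and its day 3 value lay in the lowest quartile, so the size of its fold is uncertain, and with 64 added to each intensity its log2 difference was -2.25 instead of -3.85.

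Matrix genes showed one of the largest list medians, at 0.74 against -0.20 to 0.17 in random lists, with 10 of 24 members at least 2-fold higher, 7 of them past the level filter, and 1 lower. Besides COL1A1, the small proteoglycan gene BGN was 6.33-fold higher, COL1A2 5.31-fold and the fibronectin gene FN1 3.52-fold, where COL1A2 stayed low, at intensities of 36.2 and 193. The mesenchymal gene list had a median of 0.59 against -0.26 to 0.18, with 3 of 13 members at least 2-fold higher, 0 lower and 8 above 0. Its members PRRX1 and SNAI1, both transcription factors, were 2.65-fold and 2.08-fold higher, SNAI2 differed by 0.59 in log2, and VIM, the gene of the intermediate filament vimentin, by 0.17. Epithelial genes had a median of 0.05, within the random range, and the cadherin gene CDH1 was near the lowest intensities on all 3 arrays, with 8.59 at day 3 and 9.28 in the spheres. The tight junction gene CLDN4 was 6.58-fold higher and OCLN, not past the level filter, 3.39-fold lower. Proteases and their inhibitors had a median of 0.36 against -0.26 to 0.25, with members in both directions. The collagenase gene MMP13 was 6.62-fold higher and MMP1, another collagenase, 6.25-fold lower. PDGFRB, a growth factor receptor among the stromal markers, was 8.46-fold higher, and the integrin genes ITGA7 and ITGA11 were 7.16-fold and 4.80-fold higher, although the medians of the stromal list (0.06) and of the integrins (0.23) were within the random range.

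The immediate early genes, which are transcribed within minutes to hours of a stimulus, had the highest list median at day 3, at 1.21 against -0.28 to 0.20 in random lists. Of 17 members, 9 were at least 2-fold higher, 8 of them past the level filter, and 1 at least 2-fold lower. FOSB was 29.4-fold higher, EGR2 14.2-fold, FOS 8.84-fold and ATF3 8.79-fold. FOS reached an intensity of 18729.9, against 2118 in untreated cells. Heat shock protein genes, which respond to cell stress, had a median of 0.05. Interferon-response genes had a median of 0.96 against -0.33 to 0.31, with 7 of 16 members at least 2-fold higher, 4 of them past the level filter, and 0 lower. Besides OASL, BST2 was 6.48-fold higher, RSAD2 6.03-fold and IFIT2 4.26-fold, with BST2 and RSAD2 both starting from values in the lowest quartile and not past the level filter on any array.

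Genes of cell division were lower by small amounts, and no member of either list below reached 2-fold. Mitosis genes had a median of -0.26 against -0.16 to 0.10, and 3 of 24 were above 0. DNA replication genes had a median of -0.23 against -0.16 to 0.10, with 1 of 21 above 0, and this list was within the central range of random lists that were not matched on level. The proliferation marker MKI67 was 1.67-fold lower, RRM2, a subunit of ribonucleotide reductase, 1.74-fold lower, and the cell cycle inhibitor gene CDKN1A 2.16-fold higher. CDK inhibitors and p53 targets as a list had a median of 0.16, within the random range. Housekeeping genes had a median of -0.06.

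Stem cell genes did not stand apart at day 3. The pluripotency list had a median of 0.18 against -0.32 to 0.38, with only 6 of 17 members past the level filter. POU5F1 and NANOG were low on every array, at 115 and 59.3 in untreated cells and 105 and 49.6 at day 3. SOX2 was 1.51-fold higher, KLF4 1.52-fold higher and MYC 1.23-fold lower, all short of 2-fold, and SALL4 was 2.28-fold higher. Cancer stem cell markers had a median of -0.24 against -0.30 to 0.28. Among them the drug transporter gene ABCG2 was 4.12-fold lower, PROM1, which encodes CD133, 2.85-fold lower and the chemokine receptor gene CXCR4 2.73-fold higher, while CD44 differed by -0.06 in log2. ABCG2 and PROM1 were not past the level filter, and PROM1 lay at intensities of 35.7 and 12.6, where the share of background is unknown. The osteoblast list had a median of 0.24, within the random range. The bone transcription factor gene RUNX2 was 1.20-fold higher, SPP1, which encodes osteopontin, 1.92-fold higher, and ALPL, the alkaline phosphatase gene, was low at 45.8 and 69.6.

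The largest single differences at day 3 lay partly outside these lists. DPT, which encodes the matrix protein dermatopontin, was 79.1-fold higher, the myosin light chain gene MYL10 76.7-fold, PROC, the gene of the anticoagulant protein C, 39.6-fold, and HTRA1, a secreted serine protease gene, 39.5-fold. PTGDS, a prostaglandin D synthase gene, was 31.4-fold higher, the acetylcholine receptor gene CHRNA9 21.5-fold, the folate receptor gene FOLR1 17.1-fold and RASL12 16.0-fold. PECAM1, an endothelial adhesion molecule gene, was 14.4-fold higher, while the endothelial marker list as a whole had a median of 0.00. In the other direction ANKRD1, a gene of the actin and serum response factor (SRF) target list, was 158-fold lower, with intensities of 2674 and 17.0. ANXA3 was 26.4-fold lower, NTN4 19.7-fold, the neurotrophin gene BDNF 15.8-fold, DNER 14.2-fold and EDN1, which encodes endothelin 1, 13.6-fold. HS6ST3, EVI2B, BNC1, EDIL3 and ITGBL1 were between 9.67-fold and 11.5-fold lower, and ENTPD3 differed by -3.58 in log2. In 10 of these 24 genes the lowest of the 3 values lay in the lowest quartile of all gene values, under an intensity of 63.4, where background weighs most on a fold. With noise drawn at the robust spread of the real differences, 3.63% of 9085 simulated unchanged genes passed 2-fold in either direction in this comparison. That spread includes real effects, so the share is no independent estimate of noise, and no such estimate exists with 1 array per group.

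**Figure D1:**
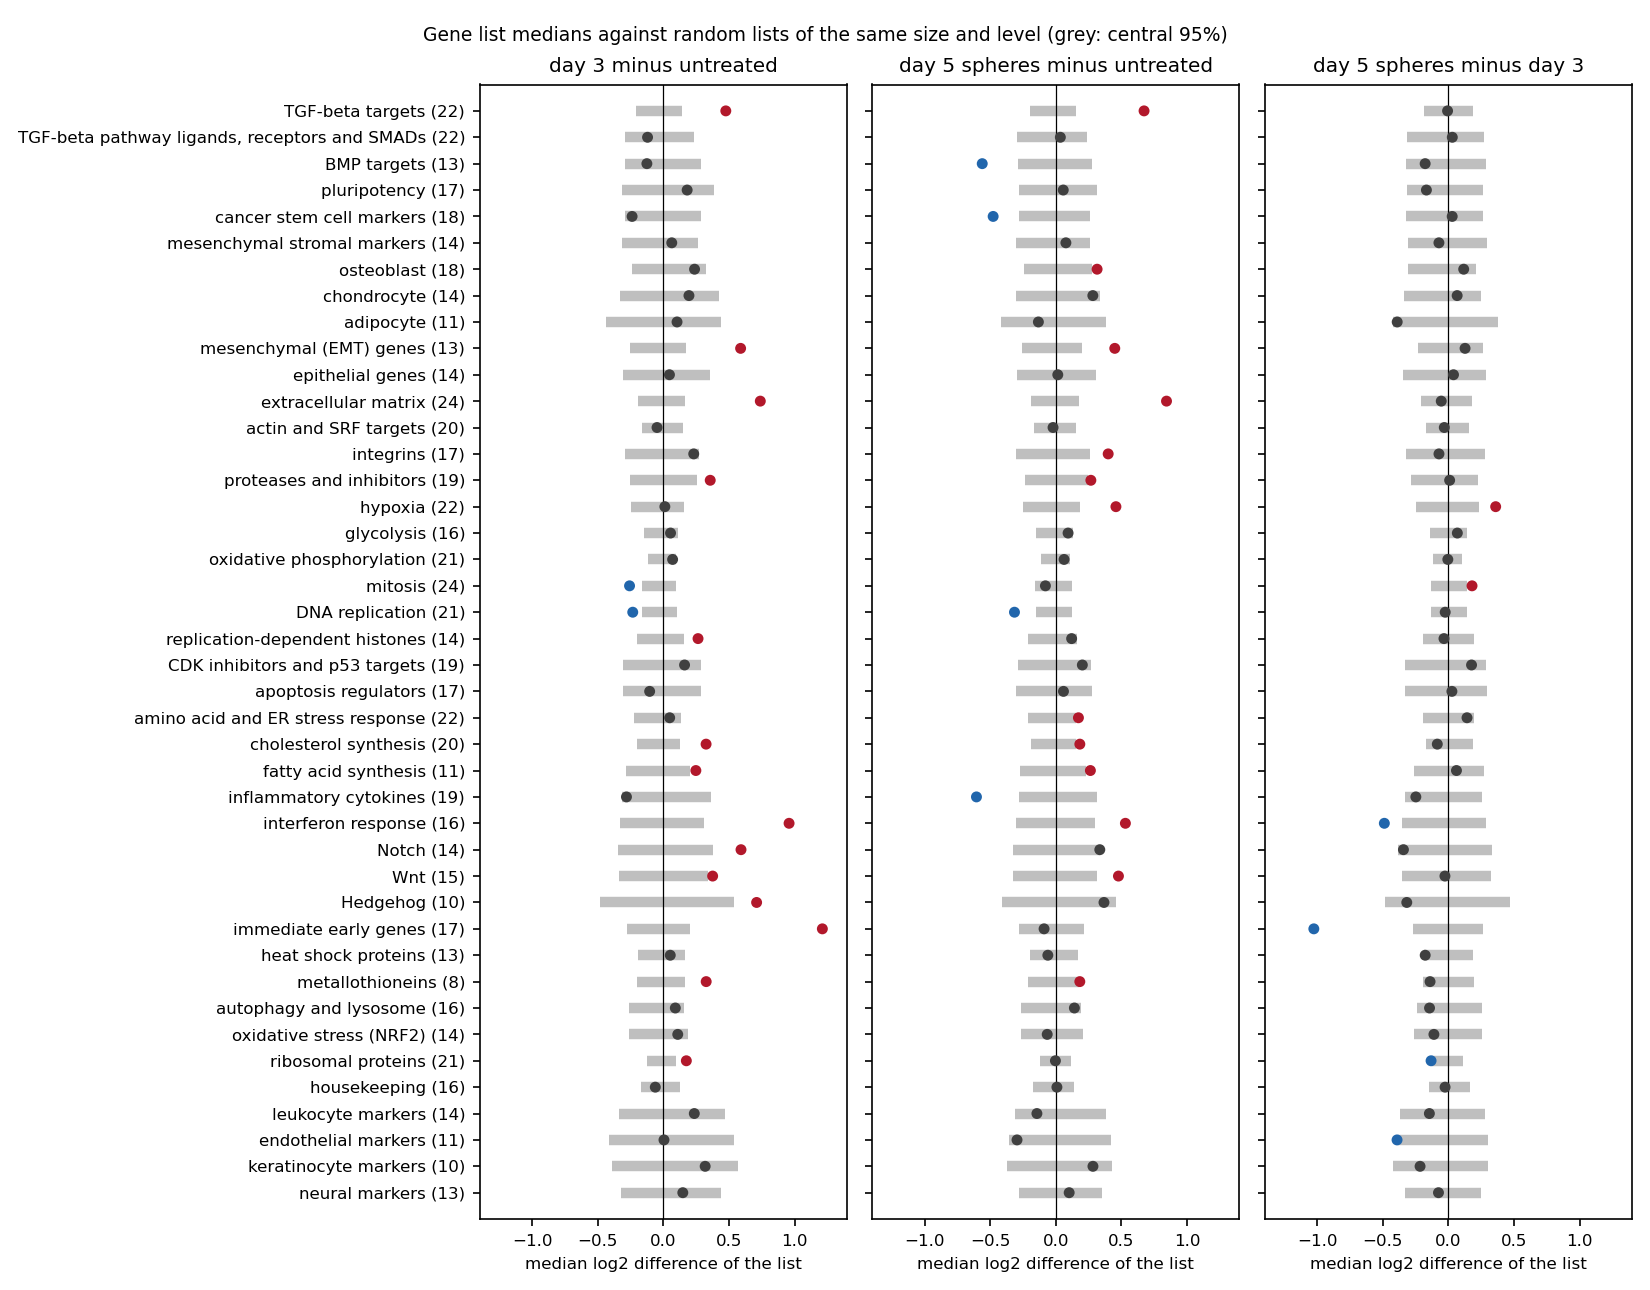
Median log2 difference (horizontal axis) of each of 42 gene lists, with the number of measured members in brackets, for the 3 comparisons. Grey bars span the central 95% of 10000 random lists matched on size and level, red points lie above that range, blue points below it and dark grey points within it; immediate early genes reached 1.21 at day 3 and -1.03 between day 5 spheres and day 3.

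The second comparison asks how spheres collected after 5 days of TGF-beta1 differed from untreated adherent cells. Matrix genes, TGF-beta targets and mesenchymal genes were higher against this same untreated array, which makes it no repeat of the day 3 result, hypoxia genes were higher, and BMP targets and inflammatory cytokine genes were lower. FN1 was 6.90-fold higher, at an intensity of 5322 against 771. NDRG1 and DDIT4, both induced by low oxygen, were 2.66-fold and 3.09-fold higher. SMAD6, an inhibitory SMAD induced by BMP, was 4.86-fold lower. DCLK1, a microtubule-associated kinase gene from the cancer stem cell list, was 193-fold higher, at 2588 in the spheres against 13.4 untreated and 23.4 at day 3. The untreated value lay among the lowest of the array, so the size of this fold is uncertain, and with 64 added to each intensity the log2 difference was 5.10 instead of 7.59. Of 9285 genes, 370 (3.99%) were at least 2-fold higher in the spheres and 409 (4.41%) at least 2-fold lower.

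TGF-beta targets had a median of 0.67 against -0.20 to 0.16 in random lists. Of 22 members, 7 were at least 2-fold higher and 1 at least 2-fold lower, with 16 above 0. TNFAIP6 was 67.1-fold higher, JUNB 4.63-fold, SPHK1, a sphingosine kinase gene, 4.17-fold and SMAD7 2.02-fold, while TGM2, which encodes transglutaminase 2, was 8.45-fold lower. The fold of TNFAIP6 starts from the same low untreated value as at day 3. TGFB1 was 1.66-fold higher, short of 2-fold. The pathway's own ligands, receptors and SMADs had a median of 0.03, within the random range. Of its 22 members, 6 were at least 2-fold lower, 5 of them past the level filter, and 2 higher, 1 of them past it. In this list FST was 9.79-fold lower and INHBA, which encodes an activin subunit, 3.11-fold higher. BMP targets had a median of -0.56 against -0.29 to 0.28, with 5 of 13 at least 2-fold lower, 3 of them past the level filter, and 2 higher. Besides SMAD6, ID4 was 6.01-fold lower and ATOH8 3.68-fold lower, both at sphere values in the lowest quartile, HEY1 was 3.34-fold higher and ID1 1.48-fold lower. Limited to the members with values in the upper quartile, the BMP list had a median of 0.03, within the random range, while its call was kept under the other 8 of 9 settings. Bright members differed in direction, with ID1 and ID3 lower and HEY1 higher. ID3, 2.30-fold lower in the spheres, was added here after its values were seen.

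Matrix genes had a median of 0.84 against -0.19 to 0.18, with 9 of 24 at least 2-fold higher, 7 of them past the level filter, and 1 lower. COL1A1 was 4.22-fold higher, BGN 4.88-fold and COL1A2, again at low intensities and not past the level filter, 6.17-fold. The mesenchymal list had a median of 0.45 against -0.26 to 0.20. PRRX1 was 4.40-fold higher and SNAI2 2.87-fold higher, ZEB2 was 2.68-fold lower, and SNAI1 differed by -0.13 in log2. The epithelial list had a median of 0.01, within the random range, while 3 members were past 2-fold. The cadherin gene CDH3 was 14.4-fold higher and CLDN4 7.43-fold, and the desmosomal gene DSP was higher by a log2 difference of 3.59. Integrin genes had a median of 0.40 against -0.30 to 0.26, and ITGA6 was 2.12-fold higher. Proteases and inhibitors had a median of 0.27 against -0.23 to 0.24, with MMP7 6.69-fold, MMP10 5.83-fold and MMP13 3.83-fold higher. Of 6 members at least 2-fold higher 2 were past the level filter, and MMP7 and MMP10 were not, at untreated intensities of 86.3 and 58.5, so their folds are uncertain in size. Actin and SRF targets had a median of -0.02, within the random range, although ANKRD1 was 16.8-fold lower and ACTA2, the smooth muscle actin gene, which was not past the level filter, 6.96-fold higher. The osteoblast list had a median of 0.31 against -0.24 to 0.27, and TNFRSF11B, which encodes osteoprotegerin, was 2.56-fold higher. With 64 added to each intensity that median was 0.11, within the random range. RUNX2 was 1.23-fold lower and SPP1 differed by 0.02 in log2.

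Hypoxia genes had a median of 0.46 against -0.25 to 0.18, with 5 of 22 members at least 2-fold higher, 0 lower and 17 above 0. PDK1, a pyruvate dehydrogenase kinase gene, was 2.42-fold higher and P4HA1, a collagen prolyl hydroxylase gene, 2.35-fold. VEGFA was 1.57-fold lower, at 4463 against 7029. Glycolysis genes had a median of 0.09 and oxidative phosphorylation genes of 0.06, both within the random range. Interferon-response genes had a median of 0.53 against -0.30 to 0.30, with 6 of 16 at least 2-fold higher, 4 of them past the level filter, and 1 lower, and IFI44 was 3.74-fold higher. Immediate early genes had a median of -0.09 against -0.28 to 0.22. Their members went both ways, with JUNB and, at 4.11-fold, EGR2 higher and KLF2 5.13-fold lower. DNA replication genes were lower by a median of -0.32 against -0.15 to 0.12, with no member past 2-fold. Mitosis genes had a median of -0.08, within the random range, and FOXM1, a transcription factor gene of mitotic entry, was 2.84-fold lower. MKI67 was 1.62-fold lower and CDKN1A 2.46-fold higher.

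Markers used for cancer stem cells were lower as a list in the spheres, with a median of -0.48 against -0.28 to 0.26. Of 18 members, 2 were at least 2-fold higher, namely DCLK1 and ITGA6, and 4 were at least 2-fold lower. The drug transporter genes ABCB1 and ABCG2 were 6.07-fold and 3.28-fold lower and MCAM 2.40-fold lower. PROM1 was 1.51-fold lower, ALDH1A1, an aldehyde dehydrogenase gene, 1.69-fold lower and CD44 1.12-fold higher. ABCG2, PROM1 and ALDH1A1 were not past the level filter. The list was within the random range when 64 was added to each intensity (-0.15), under the upper quartile level filter (-0.04) or when only members past the level filter were used (-0.34), the latter a choice made after seeing the data. Pluripotency genes had a median of 0.06 against -0.28 to 0.32, and no member reached 2-fold. Only 6 of 17 members were past the level filter, so the median says little about the rest. POU5F1 was at 80.5 and NANOG at 46.8 in the spheres, SOX2 was 1.38-fold higher, and KLF4 and MYC were 1.36-fold and 1.14-fold lower.

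Of the largest single differences in the spheres, several lay outside these lists. AMTN, which encodes the enamel matrix protein amelotin, was 59.1-fold higher, and ODAPH, a gene required for enamel mineralisation, was 17.2-fold higher. HTRA1 was 29.4-fold higher, MYL10 34.7-fold, SYNDIG1 26.1-fold, FLRT2, a cell-surface leucine-rich repeat protein gene, 23.4-fold, and DNAJC12 18.6-fold. LRFN5 was 17.8-fold higher, the microfibril gene MFAP4 15.9-fold and the transcription factor gene MSC 15.9-fold. GPRC5A, an orphan receptor gene, was 31.7-fold lower, GDA, which encodes guanine deaminase, 26.9-fold, HS6ST3 17.5-fold, SH3RF2 16.2-fold and EVI2B 15.1-fold. SKAP1 was 12.8-fold lower, INHBB, another activin subunit gene, 12.2-fold, ACOX2 11.4-fold, CPA4 9.77-fold and ADGRG6 9.08-fold. In 6 of these 24 genes the lowest value lay in the lowest quartile. In simulated data 4.10% of 9085 unchanged genes passed 2-fold in this comparison.

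**Figure D2:**
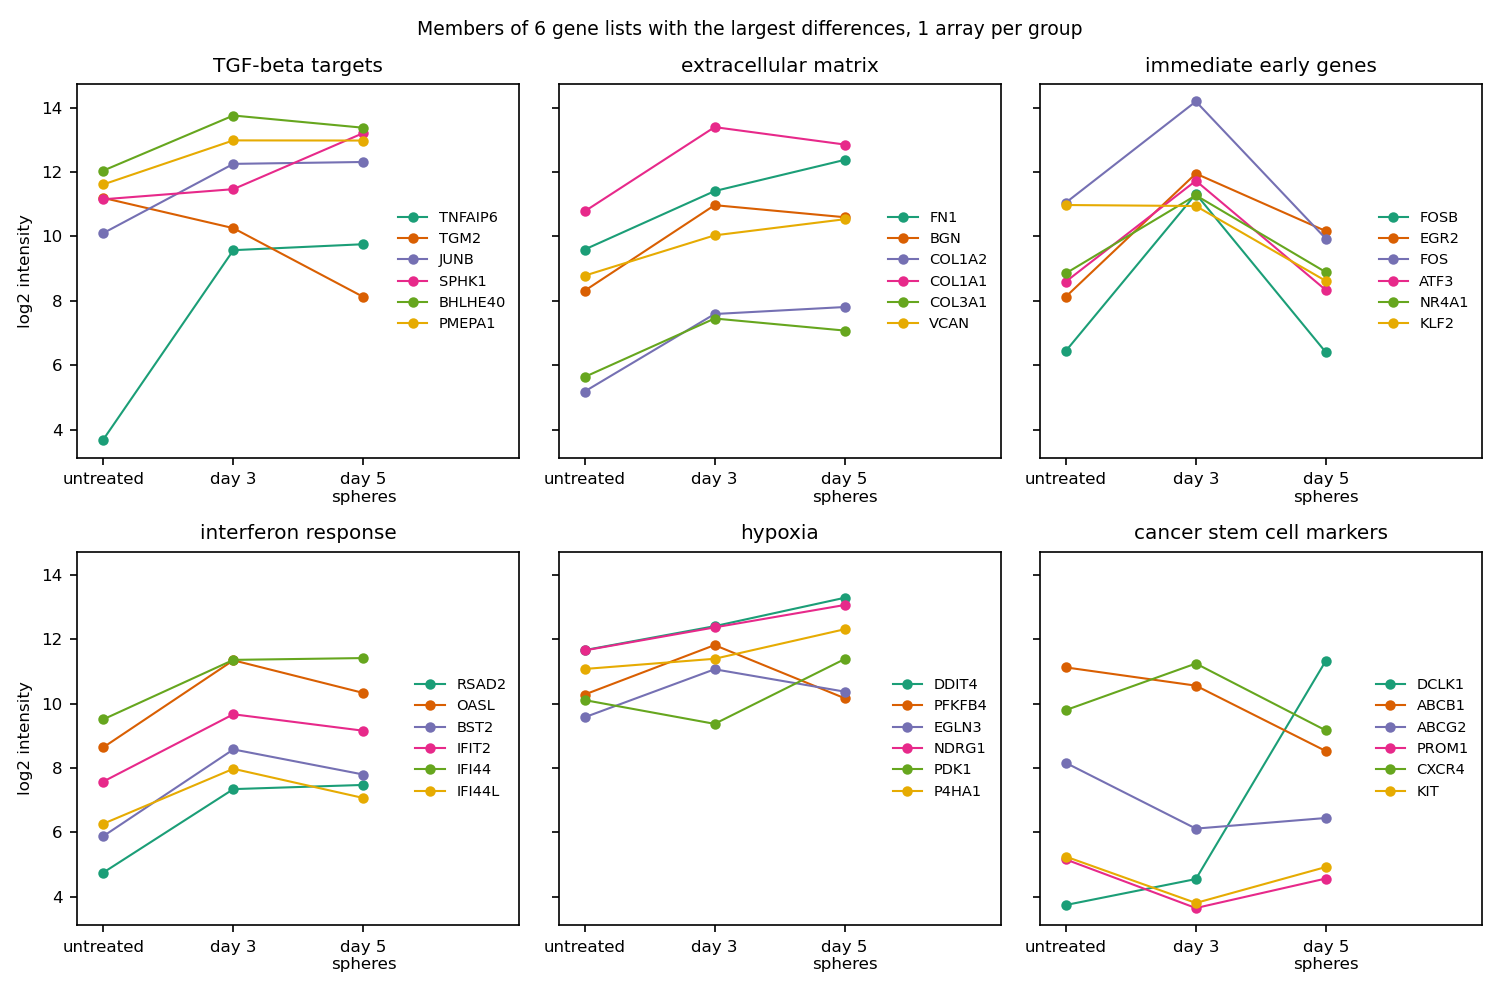
Log2 intensity (vertical axis) on the 3 arrays for the 6 members of 6 gene lists with the largest difference from untreated cells; each point is 1 array and lines join the values of a gene. FOS stood at 14.19 at day 3 against 11.05 untreated and 9.93 in day 5 spheres, and DCLK1 was low on the first 2 arrays and high in the spheres.

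Both TGF-beta1 arrays were compared with the same untreated array, so their differences overlap without any effect. The number of genes at least 2-fold higher at both times was 175, against 17.0 for independent lists and a mean of 167 (148 to 187 in the central 95%) when each gene's 3 values were shuffled among the arrays. The number at least 2-fold lower at both times was 109, against 14.1 for independent lists and 133 (115 to 151) after shuffling. The overlap of higher genes was therefore no larger than shuffling gave and that of lower genes was smaller. Shuffling keeps the real differences between the cultures, so it only asks whether the untreated array stood apart more often than the others. It cannot tell a response shared by both treated cultures from the sharing of an array. There were 20 genes past 2-fold in opposite directions, against 31.5 for independent lists and 30.3 (22 to 40) after shuffling. TNFAIP6, MYL10, HTRA1, COL1A1 and FN1 were among the genes higher at both times, and ANKRD1, HS6ST3, EVI2B and FST among those lower at both times.

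**Figure D3:**
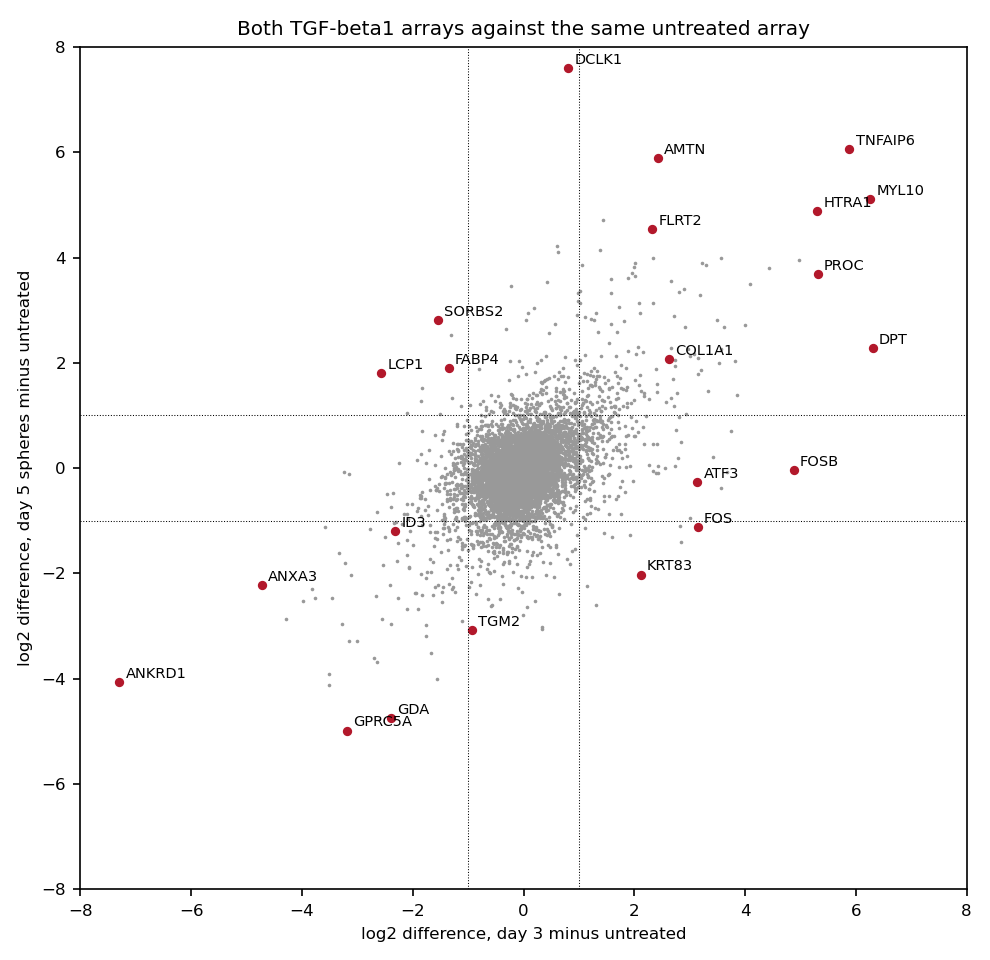
Log2 difference from untreated cells at day 3 (horizontal axis) and in day 5 spheres (vertical axis) for 9285 genes, each a grey point, with selected genes in red and dotted lines at 2-fold. Of these genes 175 lie past 2-fold in the upper right, 109 in the lower left and 20 in opposite directions; both axes share the untreated array.

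The last comparison sets the day 5 spheres against the day 3 culture. Immediate early genes and interferon-response genes were lower in the spheres, and hypoxia genes were higher. FOSB was 30.3-fold lower and FOS 19.2-fold lower in the spheres, and ATF3 and the nuclear receptor gene NR4A1 were 10.6-fold and 5.24-fold lower. TGF-beta targets and matrix genes did not stand apart between the treated arrays, with medians of -0.01 and -0.05, which low values of these genes on the untreated array alone would also give. Of 9285 genes, 424 (4.57%) were at least 2-fold higher in the spheres and 475 (5.12%) at least 2-fold lower.

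Immediate early genes had a median of -1.03 against -0.27 to 0.26, with 9 of 17 at least 2-fold lower, 8 of them past the level filter, and 0 higher. Interferon-response genes had a median of -0.49 against -0.36 to 0.29. OASL was 2.02-fold lower, and the other members stayed under 2-fold. Hypoxia genes had a median of 0.36 against -0.24 to 0.23, with 17 of 22 members above 0. PDK1 was 4.04-fold higher and the histone demethylase gene KDM3A 2.45-fold higher, while ANGPTL4 and PFKFB4 were 3.84-fold and 3.14-fold lower. Mitosis genes were higher by a median of 0.18 against -0.14 to 0.15, with 19 of 24 above 0. The only member past 2-fold went the other way, FOXM1 at 2.61-fold lower, and HMMR was 1.76-fold higher. Ribosomal protein genes had a median of -0.13 against -0.12 to 0.11, with no member past 2-fold. Both of these lists were within the range of random lists not matched on level. The mesenchymal list had a median of 0.13, within the random range, and its transcription factor genes differed in direction, with ZEB1 2.76-fold higher and SNAI1 2.28-fold lower. SNAI2 was 1.91-fold higher, short of 2-fold.

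Within lists whose medians lay inside the random range, single genes still differed. Among cancer stem cell markers, with a median of 0.03, DCLK1 was 110.4-fold higher from a day 3 value in the lowest quartile, with a log2 difference of 4.92 instead of 6.79 when 64 was added, CXCR4 4.23-fold lower, ABCB1 4.09-fold lower and ITGA6 2.68-fold higher. Among pluripotency genes, with a median of -0.17, SALL4 was 4.10-fold and KLF4 2.06-fold lower. CDH3 was 6.96-fold and DSP 4.04-fold higher among epithelial genes, whose median was 0.04. Among integrins, with a median of -0.07, ITGA7 was 5.09-fold and ITGA11 4.58-fold lower. BMP targets had a median of -0.18, with 4 of 13 members at least 2-fold lower and 3 higher. SMAD6 was 4.54-fold and BAMBI 4.25-fold lower, while SMAD9, not past the level filter, was 5.23-fold higher. The adipocyte list had a median of -0.39, within the random range. FABP4, a fatty acid carrier gene, was 9.48-fold higher and PPARG, the adipocyte transcription factor gene, 3.17-fold lower. Osteoblast and chondrocyte lists had medians of 0.12 and 0.07, within the random range.

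Other large differences between the spheres and day 3 included LCP1, an actin-bundling protein gene, 20.7-fold higher, SORBS2 20.6-fold, CPPED1 14.3-fold and EDNRA, an endothelin receptor gene, 12.8-fold higher. DNAJC12, ODAPH, AMTN, SYNDIG1 and ANKRD1 were between 9.36-fold and 12.2-fold higher, and PAPPA, a metalloproteinase gene, was 10.2-fold higher. TFF2, a trefoil factor gene, was 19.0-fold lower, DPT 16.4-fold, PDZD2 15.5-fold, RARRES2, which encodes chemerin, 15.3-fold and CGNL1, a junction protein gene, 15.2-fold lower. The hair keratin genes KRT83 and KRT81 were 17.6-fold and 15.0-fold lower, and as near-identical relatives they can share signal on an array. NR4A2 was 13.5-fold lower and TMTC1 10.5-fold lower. In 5 of these 24 genes the lowest value lay in the lowest quartile, and in simulated data 7.03% of 9085 unchanged genes passed 2-fold in this comparison.

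Markers of other cell types were examined in all 3 comparisons. Past the level filter were 2 of 14 measured leukocyte markers, 1 of 11 endothelial, 1 of 10 keratinocyte and 1 of 13 neural markers. The medians therefore rest mostly on low values and say little about these cell types. Leukocyte markers had medians of 0.24, -0.14 and -0.14 for day 3, the spheres and their direct comparison, keratinocyte markers 0.32, 0.28 and -0.22, and neural markers 0.15, 0.10 and -0.08, all within the random range. Endothelial markers had medians of 0.00 and -0.30 against untreated cells, within the random range, and -0.39 between spheres and day 3, just outside a range of -0.38 to 0.30. With 64 added to each intensity this last median was -0.06 and after the running median, a choice made after seeing the data, -0.25, both within the range.

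Across the 3 comparisons 39 of 126 list medians lay outside the central 95% of matched random lists. They were 14 above and 2 below for day 3, 13 above and 4 below for the spheres against untreated cells, and 2 above and 4 below for the spheres against day 3. By chance 6.3 would do so if the genes of a list varied independently of one another. Genes of a list can vary together, and the last comparison is the difference of the others, so the excess does not measure chance. Probe sets of the same gene gave a partial check of measurement on the arrays. Of 771 genes past the level filter with more than 1 probe set, all probe sets differed in the same direction in 75.6%, 73.7% and 79.5% of genes in the 3 comparisons, with pooled SDs between probe sets of 0.26, 0.31 and 0.37 in log2. This check covers hybridisation only, and probe sets of a gene may share probes.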

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

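The tests on heat shock genes and on the day 5 array were chosen after the result was seen, and the running median correction was added after seeing the data, with its threshold set before its result was known.

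Some genes were past 2-fold in opposite directions from untreated cells on the TGF-beta1 arrays, and the difference between the times was not tested because each has 1 array. FOS differed by 3.14 in log2 at day 3 and by -1.12 in the spheres, CGNL1 by 2.83 and -1.10, and TFF2 by 2.84 and -1.41. KRT83 differed by 2.12 and -2.02, KRT81 by 1.31 and -2.59, and TMTC1 by 1.15 and -2.25. The reverse order held for LCP1, at -2.57 and 1.80, SORBS2, at -1.55 and 2.82, CPPED1, at -1.31 and 2.52, FABP4, at -1.35 and 1.89, and PAPPA, at -1.83 and 1.52. These 11 genes were the named ones among the 20 with opposite directions, a number below the 22 to 40 that shuffling of the arrays gave.

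Among 13176 probe sets that carry no gene name here and passed the level filter for probe sets, 689 were at least 2-fold higher at day 3 than in untreated cells and 558 were at least 2-fold higher in the spheres. At the same time 703 and 619 were at least 2-fold lower, so neither direction prevailed against untreated cells. Between spheres and day 3 more were higher, 937 against 627 lower. These probe sets enter no comparison of named genes.

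FOS belongs to the immediate early genes, which were higher at day 3 than on both other arrays. After the running median of all genes at the same level was subtracted, the list's median for day 3 against untreated cells was 1.01. The random lists were already matched on level, so this largely repeats that comparison and is no separate test. A trend with intensity shared by genes of the same level does not account for the pattern. A stress of the heat shock type at harvest is argued against by the median of 0.05 for heat shock protein genes, with an upper bound of 0.20. This bound was made from the standard error over 13 genes on 1 pair of arrays. It therefore measures the spread between genes and not between cultures. A lasting response to TGF-beta1 stays open, since the list's median in the spheres was -0.09 but only floating cells were collected there. Other differences in handling at harvest, such as the time since a change of medium, could raise the same genes and were not tested.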

How the results depend on the processing

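Each number of genes past 2-fold stayed within 1.5 times its reported value under the brightest probe set, the median over probe sets, centring, quantile normalization and 64 added before log2. The probe set settings could change little, since only 1349 of 17185 genes had more than 1 probe set. Centring and quantile normalization could change little too, since the arrays already had nearly the same distribution. The same limit holds for list calls kept under these settings. Numbers depended on the level filter and the threshold, as their construction implies, and are given in the order day 3 higher and lower, spheres against untreated higher and lower, spheres against day 3 higher and lower. With no filter on low values they were 991, 904, 842, 860, 994 and 811, and with the upper quartile level filter 127, 57, 102, 97, 70 and 124. At 1.5-fold they were 908, 1003, 870, 1162, 1127 and 1225, and at 3-fold 161, 101, 145, 131, 111 and 137. Genes past 2-fold the same way at both times numbered 665 with no filter and 84 with the upper quartile filter. With each array centred on its median, 51.8% of the genes called between spheres and untreated cells were higher, against 47.5% as reported, so neither direction prevailed there.

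Of 39 list medians outside the random range, 21 stayed outside on the same side under every setting run for them. For Hedgehog genes at day 3 and interferon-response genes in all comparisons, 8 of the 9 settings were run. Random lists not matched on level ended 11 calls, the upper quartile filter 7 of 34 with enough members left, 64 added before log2 4, members past the level filter 3 of 38, the running median 2, quantile normalization 1, and the other settings none. The last filter and the running median were chosen after seeing the data. The planned setting without a filter equals the reported one, since lists use all members. BMP targets in the spheres against untreated cells reversed to 0.027 under the upper quartile filter and kept their call under the other 8 of 9 settings. The rule for naming genes took in 336 differences past 2-fold. With 64 added, 144 moved by more than the SD between probe sets and 51 came under 2-fold, among them PROM1 at day 3, SMAD7 in the spheres against untreated cells, and OASL and KLF4 between spheres and day 3. Centring brought 3, the brightest probe set 2 and quantile normalization 2 under 2-fold, and none reversed under any setting. No paired analysis was possible because each group has 1 array, and leaving out an array was not possible. Signal over background is unknown without detection calls, which limits folds from low values most.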

Other observations

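Lipid synthesis genes, developmental signalling genes and inflammatory genes also stood apart as lists. Cholesterol synthesis genes had a median of 0.33 at day 3 against -0.20 to 0.13 in random lists, with 19 of 20 members above 0 and none past 2-fold. INSIG1, a regulator of sterol synthesis, was 1.54-fold higher and IDI1, an enzyme gene of the pathway, 1.41-fold. In the spheres the list had a median of 0.18, and the sterol carrier gene STARD4 was 2.20-fold higher. Fatty acid synthesis genes had medians of 0.25 at day 3 and 0.26 in the spheres. The desaturase gene FADS2 and the fatty acid synthase gene FASN were 2.85-fold and 2.24-fold higher at day 3. In the spheres 7 of 11 members were above 0. Only 1 was past 2-fold there, the fatty acid carrier gene FABP3, at 4.15-fold higher. FASN stood at 1701 in the spheres, against 1898 in untreated cells. With the upper quartile level filter the cholesterol median in the spheres was 0.14, within the range. The calls for fatty acid synthesis genes and the one for cholesterol synthesis genes in the spheres ended with random lists not matched on level. Inflammatory cytokine genes had a median of -0.28 at day 3, within the random range, and of -0.61 in the spheres against -0.28 to 0.32, where 6 of 19 members were at least 2-fold lower, 4 of them past the level filter, and 0 higher. IL6 was 2.96-fold lower, PTGS2, which encodes cyclooxygenase 2, 2.90-fold, TNFAIP3 3.03-fold and CSF2 2.29-fold. Under the upper quartile level filter this median was unchanged but within the random range.

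Notch genes had a median of 0.59 at day 3 against -0.34 to 0.38, and of 0.49, within range, under the upper quartile level filter. At day 3 NOTCH1 was 3.57-fold higher and the ligand gene DLL4 4.81-fold lower. DLL4 was not past the level filter and stood at 39.6 at day 3, in the lowest quartile, and with 64 added its log2 difference was -1.30 instead of -2.27. The median in the spheres was 0.33, within the range, where the target genes HES4 and HEY1 were 4.12-fold and 3.34-fold higher. Wnt genes had medians of 0.38 and 0.48, above random lists, but the day 3 call was kept under only 4 of 9 settings. It ended with quantile normalization (0.34), 64 added before log2 (0.20), the upper quartile level filter (0.05), the running median (0.11) and members past the level filter only (0.05). LEF1, a Wnt target and transcription factor gene, was 3.33-fold and 3.27-fold higher on the treated arrays, WNT5A 2.29-fold and 3.40-fold, the antagonist gene DKK1 5.55-fold lower at day 3 and SFRP1 4.03-fold lower in the spheres. Hedgehog genes had a median of 0.71 at day 3, above random lists, with the co-receptor gene BOC 3.88-fold higher, and of 0.37 in the spheres, within the range. Metallothionein genes had medians of 0.33 and 0.18, histone genes 0.26 and 0.12, and ribosomal protein genes 0.18 and 0.00. Of these the values of metallothioneins at both times and of histones and ribosomal proteins at day 3 were above matched lists, and all of these calls ended with unmatched lists. Genes of the amino acid and endoplasmic reticulum stress response had medians of 0.05, within the range, and 0.17, above it, a call that ended with unmatched lists, with the upper quartile level filter (0.08) and over members past the level filter only (0.13). The only member past 2-fold in the spheres, CHAC1, was 2.96-fold lower. Apoptosis regulators (-0.10 and 0.06), autophagy and lysosome genes (0.09 and 0.14), oxidative stress genes (0.11 and -0.07), chondrocyte genes (0.20 and 0.28) and adipocyte genes (0.10 and -0.13) were within the range in both comparisons with untreated cells.

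For the patterns below, the running median correction was added after seeing the data, with its threshold set before its result, and the other tests were chosen after the result was seen. Hypoxia genes were higher in the day 5 spheres. Their median against untreated cells was 0.47 after the running median was subtracted. This largely repeats the comparison with random lists matched on level and is no separate test. A trend with intensity shared by genes of the same level does not account for the higher values. One hypothesis is that the interior of floating spheres receives less oxygen, and another is that the genes follow the day of treatment. At day 3 the list's median against untreated cells was 0.01, within the random range, but 4 of 22 members were at least 2-fold higher, among them PFKFB4 at 2.90-fold and EGLN3 at 2.81-fold. None of these 4 was at least 2-fold higher in the spheres than in untreated cells. Of the members past 2-fold in the spheres, PDK1 and KDM3A were lower at day 3 than in untreated cells. DDIT4, NDRG1 and P4HA1 were higher at day 3, all short of 2-fold. The sphere fraction rather than day of treatment as the source cannot be told apart from it, because the arrays analysed here include 0 of adherent cells after 5 days of TGF-beta1. The oxygen supply of the spheres was not measured in the data used here, and VEGFA was lower, which a plain hypoxia response may not predict.

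Interferon-response genes were higher on both TGF-beta1 arrays. The smaller of the medians against untreated cells was 0.58 after the running median was subtracted. Here too this largely repeats the comparison with lists matched on level, which already argued against a trend with intensity. Low values on the untreated array alone would raise both treated arrays alike. The list's median between spheres and day 3 was -0.49, outside the random range, so the treated arrays also differed from each other. That comparison leaves out the untreated array, so it cannot show whether low untreated values raised both. Low untreated values together with a difference between the treated cultures could give the whole pattern. With 1 array per culture a response to TGF-beta1 is a hypothesis that these data leave open.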
